A study of Homo sapiens with 23 samples.

How the data were processed

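RNA of A549, H720 and H209 cells was hybridised to 23 Affymetrix arrays of 54675 probe sets, and all 23 deposited columns were used. The deposited values were intensity, the linear probe set signal that the authors made with MAS5 per their processing notes, which give no version. The authors scaled each array, and the mean after trimming 2% at each end was about 500 in 18 arrays, about 133 in 2 (H720 control and MK886, both replicate 2) and about 20 in the 3 FLAP arrays. Each array was therefore scaled to a trimmed mean of 500, and values were used as log2(scaled signal + 32). Probe sets with a mean scaled signal of at least 100 over the arrays of a comparison were tested. Replicates of the MK886 experiments and the silenced FLAP arrays carry the numbers of the labels, so the H720 MK886 and control arrays are numbered 2, 3 and 4. The HNRPA2B1 replicates were numbered by cell line, 1, 2 and 3 for the A549, H209 and H720 pairs. Their labels number them otherwise. They read control and silenced 1 in A549, control 1 and silenced 2 in H209, and control 2 and silenced in H720. The 62 control probe sets were left out. Of the others, 41091 carried 1 gene symbol, 1801 several and 11721 were not named by the annotation, and no symbol had to be updated. Gene values and lists used the probe sets with 1 symbol, 19775 genes in all. Signal has no count behind it, so the number of arrays sets the precision.

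Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), with Benjamini-Hochberg adjustment over the probe sets of a comparison and a threshold of 0.05. MK886 was compared with control in the 6 H720 arrays without covariates and in the 8 A549 arrays with culture date, and the difference between lines was tested as an interaction in all 14. HNRPA2B1 silencing was compared with cell line as a block, with control and silenced arrays matched by the line in the label and not by its number. FLAP silencing, with 1 control array, took its spread from the 8 A549 MK886 arrays, so the lone control was assumed to vary like these. Gene groups were 32 lists with 963 genes, of which 864 had a probe set, and each gene was represented by the probe set with the highest mean log2 signal. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 32 lists. With an estimated correlation camera called 0 lists in each of the 5 comparisons, and fry called 0 in H720, 1 in A549, 0 for the difference, 0 for HNRPA2B1 and 3 for FLAP. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes. The p-values measure the spread between arrays, which may be technical, since apart from the 2 A549 dates the labels do not say that replicates were separate cultures.

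The comparisons, tests, lists, alternatives and the rule for naming genes were set before the data were examined. HNRNPA2B1 and ALOX5AP were always named. Per comparison, the 10 genes with the largest rise and the 10 with the largest fall were taken among called probe sets with 1 symbol and complete separation of treated from control arrays (within date for A549, within line for the pairs). Where fewer than 20 genes passed, the 10 with the smallest unadjusted p in each direction under the same separation were taken and described as not passing. In the FLAP comparison 22 genes passed, 1 of them lower. For the difference between lines no separation was required. The 4 members with the smallest p were taken from each called list, and 2 from any other list described. RNA integrity was read as the ratio of the 5' to the 3' probe set of ACTB and GAPDH, and compared by an exact two-sided permutation test. This test took no account of dates or pairs.

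Whether replicate numbers pair arrays was checked by correlating the arrays after removal of group means. In H720 arrays of the same number correlated at r = 0.44, 0.23 and 0.25, in A549 at 0.44, 0.36, 0.38 and 0.52, where other pairs of the same date were as close, and in the HNRPA2B1 pairs at 0.81, 0.58 and 0.53. A block of pairs was therefore run as an alternative. It is given only where it changed a call or moved the number of small p-values well above that expected by chance. The fits were tested on simulated data with 100 probe sets shifted 2-fold and 100 shifted 4-fold. In H720 11 and 59 were recovered (4 false calls), in A549 52 and 84 (8), for the difference 15 and 46 (2), for the HNRPA2B1 pairs 34 and 76 (12) and for FLAP 9 and 45 (2). A simulated shift of 0.5 in 1 list was called by fry and by camera at the preset correlation in all 5 comparisons, and by camera at an estimated correlation in 3 (not in H720 nor for HNRPA2B1), with 0 other lists called. Each simulated probe set varied independently of the others. The false calls and the 0 other lists therefore do not show how often correlated genes are called falsely. Each simulated array, the lone FLAP control included, had the spread that the fit assumes. The simulation thus does not test whether that control varies like the MK886 arrays. It also left out what the H720 arrays numbered 2 share.

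Alternatives were the deposited scale, quantile normalization, pseudocounts of 8 and 100, no filter and a filter at 300, eBayes without a trend, blocks or covariates added or removed, each date alone, each array left out and other list tests. Another 8 alternatives were chosen after seeing the data, namely the deposited scale as a block, replicates 3 and 4 alone and the ACTB ratio as a covariate in H720, the scale block and the removal of both H720 arrays numbered 2 for the difference, date with the ACTB ratio in A549, the silenced FLAP arrays against 5 other A549 controls, and camera with a trend of the variance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.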

Results

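RNA levels were measured in cultured human lung tumour lines on 23 Affymetrix oligonucleotide arrays, each reading 54675 probe sets, which are sets of short probes for a transcript, with some shared by several genes. A549 is a lung adenocarcinoma line, H720 a line from a lung carcinoid tumour with neuroendocrine features, and H209 a small cell lung cancer line. Per the labels, 3 H720 arrays carried control RNA and 3 carried RNA of cells given MK886 at 1 micromole for 24 h in serum-free medium. MK886 is a small molecule that binds FLAP, the protein that hands arachidonic acid to 5-lipoxygenase for leukotriene synthesis. A549 cells gave 4 control and 4 MK886 arrays, made as duplicates on 2 dates, with no dose in the labels. Silencing of HNRPA2B1 (gene symbol HNRNPA2B1), an RNA-binding protein of mRNA processing and transport, was measured in 1 control and 1 silenced array each of A549, H209 and H720. Silencing of FLAP (gene symbol ALOX5AP) by siRNA was measured in 1 control and 2 silenced A549 arrays. After scaling, 44.1% to 65.5% of the probe sets of an array reached a signal of 100, and the median signal of an array lay between 76.9 and 190.6. The number of arrays limits the precision of every value below.

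HNRNPA2B1 messenger RNA stood lower after silencing in all 3 cell lines. The brightest of its 3 probe sets fell by 0.83 on the log2 scale (SE 0.14), from a scaled signal of 34094 ± 1791 (SD, n = 3) to 19371 ± 3448 (SD, n = 3). The signal left was 45.0% of the control in A549, 62.3% in H209 and 63.6% in H720. The next probe set fell by 0.88 (SE 0.14), from 3955 ± 1517 to 2123 ± 778, with log2 changes of -0.92, -0.91 and -0.82 in the same order. The weakest fell by 0.66 (SE 0.28), with 89.5%, 37.3% and 76.2% left. Adjusted over these 3 probe sets alone, limma gave an adjusted p = 0.000132 for the first and second and 0.0372 for the third. Over all probe sets tested the adjusted p-values were 0.770, 0.770 and 0.939, past no threshold. In the arrays without this silencing the brightest probe set ranged from 24847 in an H720 MK886 array to 37874 in the FLAP control, above each silenced array. This did not hold for the other probe sets. In the next one the silenced H209 array (3021) lay above A549 MK886 control replicate 3 (2852) and MK886 replicate 3 (2879). In the weakest, A549 MK886 replicate 3 (271) lay below each silenced array (277 to 599).

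**Figure D1:**
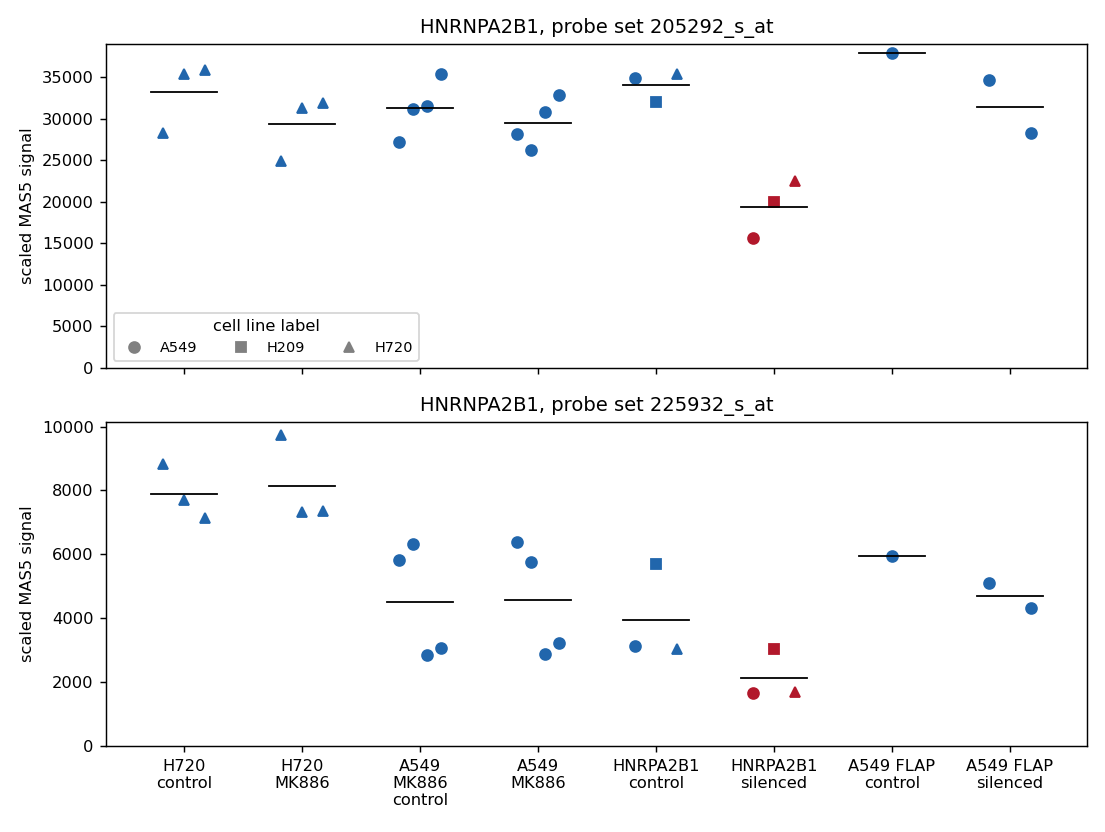
Scaled signal of the brightest and the next HNRNPA2B1 probe set in each of the 23 arrays (points, marker by cell line, silenced arrays in red), with the mean of each group as a black line. In the brightest probe set the 3 silenced arrays lay between 15668 and 22488, below the other 20 arrays. In the next probe set the silenced H209 array (3021) lay above A549 MK886 control replicate 3 (2852) and MK886 replicate 3 (2879).

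No fall of ALOX5AP, the gene for FLAP, was detectable with these arrays. Its probe set had a scaled signal of 208 in the FLAP control and of 181 and 210 in the silenced arrays, a log2 change of -0.078 (SE 0.57) with a 95% interval from -1.30 to 1.14. In the 4 other A549 control arrays of the MK886 experiment its signal was 210.3 ± 115 (SD, n = 4), at percentile 61.4 of all probe sets. An interval of this width leaves open both a fall and a rise of more than 2-fold.

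In H720 cells MK886 was accompanied by higher messenger RNA of the amino acid deprivation and ER stress response, the genes driven by the transcription factors ATF4 and CHOP. All 29 measured members of this list stood higher, with a median log2 change of 0.76, and 19 rose when adjusted over the list alone, against 0 over all probe sets tested. The list was higher than the other genes with camera (adjusted p = 1.06e-20), while the adjusted p = 0.848 with an estimated correlation. NUPR1, a stress-induced chromatin protein, stood at 1002 ± 412 in the control and 3071 ± 1035 in the treated arrays (SD, n = 3 each), a log2 change of 1.61 (SE 0.32). SESN2, which restrains mTORC1 when leucine is short, changed by 1.43 (SE 0.29) on the log2 scale, SLC7A5, an amino acid transporter, by 0.85 (SE 0.18), and WARS1, the tryptophan tRNA ligase, by 0.96 (SE 0.21). DDIT3, which encodes CHOP itself and was singled out after its values were seen, also rose over the list alone, by 1.26 (SE 0.34). The median of the list was 1.28, 0.44 and 0.46 in the pairs of replicates 2, 3 and 4. The control arrays of this comparison are not labelled serum-free, and the 5' to 3' signal ratio of ACTB, a measure of RNA integrity, was 0.618 ± 0.0546 in the control and 0.317 ± 0.0491 in the MK886 arrays. That of GAPDH was 0.964 in the control and 0.720 in the MK886 arrays. An exact two-sided permutation test gave p = 0.1 for each ratio, the smallest that 3 against 3 arrays allow, and 0.3 after adjustment over 6 such tests.

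Ribosomal protein genes stood higher and cell cycle and respiratory chain genes lower with MK886 in H720, and all but the last mostly in the replicate 2 pair. The 40 ribosomal protein genes had a median of 0.29, with 39 higher (camera adjusted p = 0.00189, and adjusted p = 0.982 with an estimated correlation), as with RPL9 at 0.44 (SE 0.30) and RPS16 at 0.42 (SE 0.31). Of 50 G2/M and mitosis genes 39 stood lower, with a median of -0.20 (adjusted p = 5.32e-05, and adjusted p = 0.982 with an estimated correlation). CCNB1, the cyclin of mitotic entry, stood at -0.54 (SE 0.28) and MAD2L1, a spindle checkpoint protein, at -0.53 (SE 0.21), while FOXM1, a transcription factor of the same list, stood at 0.71 (SE 0.28) (-1.26 with the ACTB ratio as a covariate). The G1/S and DNA replication list had a median of -0.12, 33 of 46 lower (adjusted p = 0.00526), with MCM10, a replication initiation factor, at -0.58 (SE 0.23) and CDKN1A, an inhibitor of cyclin-dependent kinases, at 0.92 (SE 0.39). The oxidative phosphorylation list had a median of -0.10, 30 of 43 lower (adjusted p = 0.0147), with NDUFB3 of complex I at -0.64 (SE 0.35). With an estimated correlation the adjusted p = 0.982 for both of these lists. No member of the 4 lists passed the test, over all probe sets or adjusted over the list alone. By pair the ribosomal medians were 0.79, -0.027 and 0.023, the G2/M medians -0.55, 0.028 and -0.020 and the G1/S medians -0.48, 0.11 and -0.022 for replicates 2, 3 and 4. Without MK886 replicate 2 the 4 medians were 0.28 for ribosomal proteins, -0.021 for G2/M, 0.095 for G1/S and 0.14 for oxidative phosphorylation, and no call was left. The ribosomal call was also lost without control replicate 2 (median 0.023) and under quantile normalization (0.016), the G1/S call without control replicate 4 (-0.077), and the oxidative phosphorylation call without control replicate 3 (-0.017) or 4 (-0.021) and with the ACTB ratio as a covariate (-0.071, adjusted p = 0.928). With replicates 3 and 4 alone, which like that covariate was added after the data were seen, the ribosomal (-0.010), G2/M (-0.039) and G1/S (0.020) calls were lost. The ACTB ratio moved by -0.182, -0.354 and -0.367 in the pairs of replicates 2, 3 and 4, and both arrays numbered 2 were deposited at a lower scale than the rest.

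Among single H720 genes none passed the test. Of 26923 probe sets tested by limma, 0 were past the threshold (smallest adjusted p 0.936), 1384 had an unadjusted p under 0.05 (688 higher, 696 lower), and about 1346 would be expected by chance. Complete separation of the 3 MK886 from the 3 control arrays held for 11.1% of them, where chance gives 10%. With the replicate numbers as a block of pairs limma again called 0, but 2942 had an unadjusted p under 0.05. With the deposited scale as a block, added after the data were seen, it called 0, with 4165 under 0.05. The count near chance thus belongs to the fit without a block, from which the genes below were named. The smallest p-values among higher genes belonged to FUT1, a fucosyltransferase of blood group H antigen synthesis, which stood at 258 ± 66.6 in the control and 852 ± 116 in the MK886 arrays, a log2 change of 1.63 (SE 0.26). ATF5, a relative of ATF4 and itself a stress-response factor, stood at 1.38 (SE 0.27), and SLC43A1, an amino acid transporter, at 0.96 (SE 0.19). RPRD2, MAST2, SLC35F6, HDLBP and CIZ1 stood between 0.84 and 1.66. Among lower genes were AMD1, the decarboxylase of polyamine synthesis, at -1.04 (SE 0.19), CDK1, the kinase of mitotic entry, at -0.98 (SE 0.19), CCNE2, a cyclin of S phase entry, at -1.09 (SE 0.22) and PRPS2, which makes the ribose precursor of nucleotides, at -1.14 (SE 0.24). AP1S1, AP1S3, GATC, LARP4, PEG10 and ENSA stood between -1.84 and -0.96, and other probe sets of RPRD2, SLC35F6, GATC and PEG10 had changes of the other sign. With the ACTB ratio as a covariate, added after the data were seen, SLC35F6 (-0.86), CCNE2 (0.015), AP1S3 (0.80) and PRPS2 (0.15) had the other sign. Without MK886 replicate 2, 1 probe set was higher and 5 were lower past the threshold, and with replicates 3 and 4 alone, also added after the data were seen, 2863 and 2673.

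**Figure D2:**
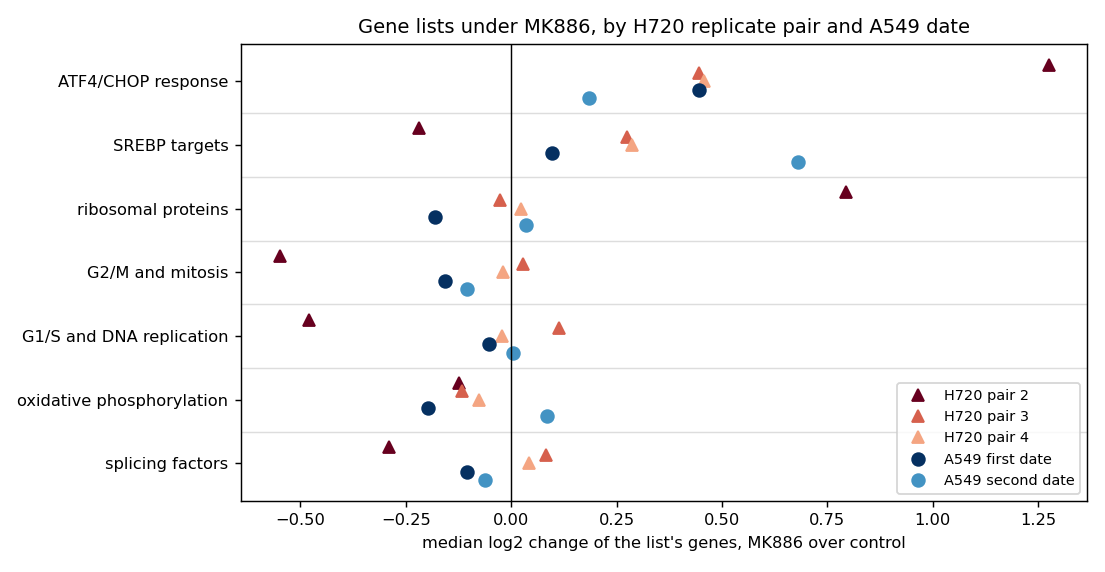
Median log2 change (MK886 minus control) of 7 gene lists in the H720 pairs of replicates 2, 3 and 4 and in A549 on the first and second date, 1 marker per pair or date. The amino acid deprivation list lay above 0 in all 5, from 0.18 to 1.28, while the ribosomal list lay at 0.79 in H720 replicate 2 and between -0.18 and 0.035 elsewhere.

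In A549 cells MK886 was accompanied by higher levels of the ATF4 and CHOP list and of the list of cholesterol and fatty acid synthesis genes. The ATF4 and CHOP list had a median log2 change of 0.32, 25 of 30 members higher, and 11 rose when adjusted over the list alone, against 0 over all probe sets (camera adjusted p = 5.16e-10, and adjusted p = 0.212 with an estimated correlation). PHGDH and PSAT1, which catalyse the first and second step of serine synthesis, changed by 0.94 (SE 0.18) and 0.67 (SE 0.13), ASNS, asparagine synthetase, by 0.86 (SE 0.17) and ATF4 itself by 0.43 (SE 0.099). PHGDH stood at 930 ± 509 in the control and 1683 ± 436 in the treated arrays (SD, n = 4 each). The list of cholesterol and fatty acid synthesis genes, targets of the SREBP factors, had a median of 0.38 with 25 of 26 members higher, and 4 rose over the list alone against 0 over all (adjusted p = 5.81e-08, and adjusted p = 0.835 with an estimated correlation). These were MVD, an enzyme of the mevalonate pathway, at 1.52 (SE 0.40), SREBF2, the factor of sterol synthesis, at 0.72 (SE 0.20), FASN, fatty acid synthase, at 0.51 (SE 0.15) and DHCR7, the last enzyme of cholesterol synthesis, at 0.69 (SE 0.21). In MK886 replicate 2 SREBF2 stood at 1133, against 567 to 634 in the other MK886 arrays. By date the ATF4 medians were 0.44 on the first and 0.18 on the second date, and the SREBP medians 0.096 on the first and 0.68 on the second date. On the first date alone the SREBP list was not called (adjusted p = 0.0927). The ACTB 5' to 3' ratio was 0.620 ± 0.179 in the control and 0.676 ± 0.112 in the MK886 arrays (exact two-sided permutation p = 0.6, adjusted 0.7 over 6 tests), and that of GAPDH was 0.960 and 0.981. That test ignored the dates. On the first date the ACTB ratio was 0.463 and 0.473 in the control and 0.579 and 0.579 in the MK886 arrays. On the second date it was 0.817 and 0.728 against 0.786 and 0.759.

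Mitosis genes stood slightly lower in A549 with MK886. Of 50 G2/M genes 40 were lower, with a median of -0.14 (adjusted p = 4.14e-05, and adjusted p = 0.354 with an estimated correlation), and 0 passed over the list alone. PTTG1, the securin that delays the separation of sister chromatids, stood at -0.29 (SE 0.095), CCNB2, a mitotic cyclin, at -0.25 (SE 0.10) and KIF20A, a kinesin of cytokinesis, at -0.27 (SE 0.11), while CDC25B, a phosphatase of mitotic entry, stood at 0.34 (SE 0.11). The medians were -0.16 on the first and -0.10 on the second date, where the list was not called on the second date alone (adjusted p = 0.216). Ribosomal proteins (median -0.082, 36 of 40 lower, adjusted p = 0.00889, and adjusted p = 0.863 with an estimated correlation), among them RPL34 at -0.24 (SE 0.12), had medians of -0.18 on the first and 0.035 on the second date. Splicing factors (median -0.083, 31 of 46 lower, adjusted p = 0.0404, and adjusted p = 0.348 with an estimated correlation), among them CLK1, a kinase of SR proteins, at -0.39 (SE 0.18), had medians of -0.10 on the first and -0.061 on the second date. The ribosomal call was lost without control replicate 1 (median -0.047) or 2 (-0.061), without MK886 replicate 1 (-0.015) or 4 (-0.079) under quantile normalization (-0.031), on the second date alone and with date and the ACTB ratio as covariates, added after the data were seen (-0.019, adjusted p = 0.487). The splicing call was lost with the replicate numbers as a block of pairs (median unchanged at -0.083, adjusted p = 0.0752), without control replicate 1, 2 or 3 (medians -0.064, -0.066 and -0.061) and without MK886 replicate 1, 2 or 4 (-0.081, -0.042 and -0.075). It was also lost with quantile normalization (-0.085, adjusted p = 0.0530), no filter (-0.083, 0.0824) and no date covariate (-0.083, 0.121). The second date alone (adjusted p = 0.550) and date with the ACTB ratio (-0.066, adjusted p = 0.452) ended it too, 12 of 20 settings in all.

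No single A549 gene passed the test over all probe sets. Limma called 0 of 31895 (smallest adjusted p 0.968), with 1462 at an unadjusted p under 0.05 (810 higher, 652 lower) and about 1595 expected by chance. EPHX1, microsomal epoxide hydrolase and a member of the NRF2 list, rose over that list alone by 0.59 (SE 0.15), although the list was not called (median -0.021, adjusted p = 0.978). Beyond members of the lists above the smallest p-values among higher genes included SLC25A22, a mitochondrial glutamate carrier, at 1.42 (SE 0.31), NIBAN1, a stress-induced regulator of translation, at 1.02 (SE 0.23) (698 in MK886 replicate 2 against 498 to 509 in the others), MKNK2, a kinase of the translation factor eIF4E, at 1.08 (SE 0.24) and NADSYN1, which makes NAD, at 0.74 (SE 0.18). Among lower genes were RHEX, a regulator of erythroid expansion, which went from a mean signal of 340 to 92.5, CAV1, the coat protein of caveolae, at -0.44 (SE 0.10) and NUSAP1, a spindle protein, at -0.41 (SE 0.11). ASRGL1 went from 1059 to 546, and PPIG, WASHC4 and SNHG19 stood between -0.60 and -0.52. RHEX, DNAH1 and PPA2 ended under 100 on average, as did POU2F2 in 3 of 4 arrays (49.0 to 69.3, and 218 in replicate 2). DNAH1 went from 222 to 60.3 and PPA2 from 194 to 38.5, and other probe sets of both had the other sign. Without control replicate 3, 6 probe sets were higher and 1 was lower past the threshold, and on the first date alone 1 and 1.

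The difference between the lines was tested as the A549 change minus the H720 change. The change of the ATF4 and CHOP list was lower in A549 than in H720, by a median of -0.49, with 24 of 30 members on that side (camera adjusted p = 4.34e-05, and adjusted p = 0.942 with an estimated correlation). By pair the list stood at 1.28, 0.44 and 0.46 in H720 replicates 2, 3 and 4, and by date at 0.44 and 0.18 in A549, so the difference was largest against the replicate 2 pair. GDF15, a stress-induced cytokine, had a difference of -1.57 (SE 0.59), CEBPB, a transcription factor, of -1.06 (SE 0.31) and SLC7A5 of -0.57 (SE 0.20). The ribosomal protein list differed by a median of -0.35, on the same side in 40 of 40 genes (adjusted p = 5.79e-07, and adjusted p = 0.942 with an estimated correlation), with RPL9 and RPS16 at -0.53 (SE 0.29) and -0.53 (SE 0.31). No member of either list passed the test of the difference. For the SREBP list the difference was 0.22 (adjusted p = 0.0514, and adjusted p = 0.942 with an estimated correlation), and with the replicate numbers as a block of pairs the adjusted p was 0.0111. Its medians were -0.22, 0.27 and 0.29 in H720 replicates 2, 3 and 4 and 0.096 and 0.68 on the first and second A549 date. In replicates 3 and 4 the SREBP list thus stood higher than in A549 on the first date. The metallothionein list had a difference of 0.42 (adjusted p = 0.0731, and 0.0250 with the block of pairs), where the adjusted p = 0.942 with an estimated correlation and no block. Its medians were -0.72, 0.018 and 0.15 in H720 replicates 2, 3 and 4 and 0.24 and 0.24 by A549 date. The difference thus lay mainly against the replicate 2 pair. Limma called 0 of 31162 probe sets (smallest adjusted p 0.854), with 1382 at an unadjusted p under 0.05 and about 1558 expected by chance. With the replicate numbers as a block of pairs limma called 0, but 2354 had an unadjusted p under 0.05. With the deposited scale as a further block, added after the data were seen, it called 0, with 2735 under 0.05. The genes below come from the fit without these blocks. Genes with the smallest p-values were PRPS2 at 1.43 (SE 0.27), GNG4, a G protein subunit, at 1.41 (SE 0.28), AMD1 at 1.01 (SE 0.22), CDK1 at 0.85 (SE 0.20) and STIP1, a co-chaperone, at 1.36 (SE 0.32). On the other side were LAMC1, a laminin chain (control to MK886, 25.8 to 145 in H720 and 1211 to 899 in A549), and TFPI, an inhibitor of coagulation (2.54 to 38.9 and 3711 to 3457). Both had H720 control signals under 100, so no change is given. SLC43A1 stood at -1.17 (SE 0.27) and SLC7A11, the cystine transporter, at -0.81 (SE 0.21). Without H720 control replicate 2, 21 probe sets were past the threshold on the higher and 4 on the lower side, the ATF4 call was lost (median -0.42, adjusted p = 0.0505) and so was the ribosomal call (median -0.077). Without H720 MK886 replicate 2 the counts were 81 and 13 and the ATF4 median -0.30 (adjusted p = 0.0757), and quantile normalization ended the ribosomal call (median -0.017). With both H720 arrays numbered 2 left out, added after the data were seen, 578 were called, 445 of them on the higher side, and both list calls were lost (ATF4 median -0.21, ribosomal median -0.089, adjusted p = 0.758 for each). The A549 dose is not in the labels, so the lines were not compared at a known equal dose.

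Silencing of HNRNPA2B1 was accompanied by lower levels of cell cycle genes. All 50 measured G2/M genes stood lower, with a median log2 change of -0.40 (camera adjusted p = 5.08e-11, and adjusted p = 0.851 with an estimated correlation). PLK1, the kinase of spindle assembly, stood at -1.09 (SE 0.30), CENPA, the centromere histone, at -0.69 (SE 0.20) and BUB1B, a spindle checkpoint kinase, at -0.60 (SE 0.18). Of 47 G1/S genes 40 were lower, with a median of -0.26 (adjusted p = 0.00116, and adjusted p = 0.851 with an estimated correlation). MCM7, a subunit of the replicative helicase, stood at -0.73 (SE 0.24) and TK1, thymidine kinase, at -0.55 (SE 0.16). By line the G2/M medians were -0.87, -0.22 and 0.0086 and the G1/S medians -0.74, 0.16 and -0.093 in A549, H209 and H720, where 1 pair per line allowed no test of a difference between lines. CXCL8 and CXCL2, which attract neutrophils, rose over the list of NF-kB and inflammatory cytokines alone (2 of 26, against 0 over all). CXCL8 had a log2 change of 1.79 (SE 0.29). CXCL8 stood at 1092 in the control and 4805 in the silenced array of A549, 33.7 and 273 in H209, where the control lay near the background, and 237 and 530 in H720. CXCL2 stood at 1974 and 5766 in A549, 22.1 and 67.3 in H209 and 29.4 and 187 in H720, with both of the last controls near the background. The list itself had medians of 0.36, -0.058 and 0.21 in these lines and of 0.17 over all 3, with 15 of 26 higher (adjusted p = 0.0268, and adjusted p = 0.851 with an estimated correlation).

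RNA-binding protein, glycolysis and growth factor feedback lists were also called after HNRNPA2B1 silencing. The hnRNP family had a median of -0.14, 22 of 25 lower (adjusted p = 0.0388, and adjusted p = 0.851 with an estimated correlation). This list holds the silenced gene itself, so its test partly restates the silencing, and the list was not tested without that gene. HNRNPA2B1 was the 1 member that fell over the list alone, with RALY, another RNA-binding protein, at -0.49 (SE 0.18). Splicing factors had a median of -0.17, 36 of 46 lower (adjusted p = 0.0146, and adjusted p = 0.851 with an estimated correlation). U2AF2, which binds the polypyrimidine tract, stood at -0.48 (SE 0.19), while PRPF3 of the spliceosome stood at 0.49 (SE 0.19). Glycolysis genes had a median of -0.20, 16 of 18 lower (adjusted p = 0.0101, and adjusted p = 0.851 with an estimated correlation). ALDOC, an aldolase, fell over that list alone, with a change of -1.30 (SE 0.32), while LDHB, a lactate dehydrogenase subunit, stood higher, with controls under 100 in H209 and H720. EGFR and MAPK feedback genes had a median of 0.24, 18 of 22 higher (adjusted p = 0.0101, and adjusted p = 0.851 with an estimated correlation). DUSP5, an ERK phosphatase, stood at 0.93 (SE 0.38), and SPRY2, an inhibitor of the pathway, stood higher, with controls under 100 in H209 and H720. Ribosomal proteins had a median of 0.15, 35 of 40 higher (adjusted p = 0.0101, and adjusted p = 0.851 with an estimated correlation). The ATF4 and CHOP list had 0.19, 23 of 30 higher (adjusted p = 0.0484, and adjusted p = 0.851 with an estimated correlation), with TRIB3, a pseudokinase of that response, at 0.86 (SE 0.30). Without the A549 pair 8 of the 9 called lists lost the call, with medians of -0.14 for G2/M, -0.033 for G1/S, -0.15 for NF-kB, -0.044 for hnRNP, -0.081 for splicing, -0.17 for glycolysis, -0.059 for EGFR and MAPK and -0.11 for ATF4 genes. Without the H209 pair the ATF4 (0.26) and ribosomal (0.13) calls were lost, and without the H720 pair those of glycolysis (-0.13), ribosomal proteins (0.14), hnRNP (-0.14) and splicing (-0.18). Quantile normalization ended the ATF4 (0.19) and ribosomal (0.042) calls, and no filter the ATF4 (0.18) and NF-kB (0.17) calls. Without the cell line block those of ATF4 (adjusted p = 0.253), NF-kB (0.359), hnRNP (0.0838) and EGFR and MAPK (0.222) were lost. The ACTB 5' to 3' ratio was 0.660 ± 0.155 in the control and 0.583 ± 0.210 in the silenced arrays (exact two-sided permutation p = 0.7, where 0.1 is the smallest possible, adjusted 0.7 over 6 tests). That test ignored the pairs. By pair the ratio went from 0.835 to 0.776 in A549, from 0.602 to 0.613 in H209 and from 0.542 to 0.359 in H720.

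Over all probe sets no gene passed the test for HNRNPA2B1 silencing. Limma called 0 of 35057 (smallest adjusted p 0.770), with 1657 at an unadjusted p under 0.05 (789 higher, 868 lower) and about 1753 expected by chance, and 25.4% had 1 sign in all 3 lines, where chance gives 25%. FLOT1, a scaffold protein of membrane rafts, stood at 608 ± 269 in the control and 78.3 ± 1.21 in the silenced arrays (SD, n = 3 each), the latter under 100, and stood lower in 4 of 4 probe sets. LGALS1, galectin-1, stood at -0.87 (SE 0.16), LMNA, which encodes lamins of the nuclear envelope, at -0.96 (SE 0.20), S100A10, a partner of annexin A2, at -0.82 (SE 0.17) and FSCN1, an actin bundling protein, at -1.01 (SE 0.23). PLCD1, CANT1 and NIPSNAP1 stood between -1.56 and -0.68, where S100A10 and PLCD1 ended at 70.9 and 91.5 in H209. ZGPAT ended at 84.7 in A549 and 86.2 in H720. Among higher genes BCHE, butyrylcholinesterase, stood at 1.74 (SE 0.32), ASAH1, acid ceramidase, at 0.60 (SE 0.14), and TFF1, a secreted trefoil protein, at 1.22 (SE 0.29) (64.2 in the H209 control). THSD7A and SERINC5 stood at 1.19 and 1.02. FLRT3, a cell adhesion protein, LINC02582 and IZUMO4 stood higher with control signals under 100 in H209 and H720 (82.6 and 83.0, 31.6 and 35.7, 36.7 and 83.2). Without the A549 pair 3 probe sets were higher and 10 lower past the threshold, and without the H209 pair 10 and 7.

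**Figure D3:**
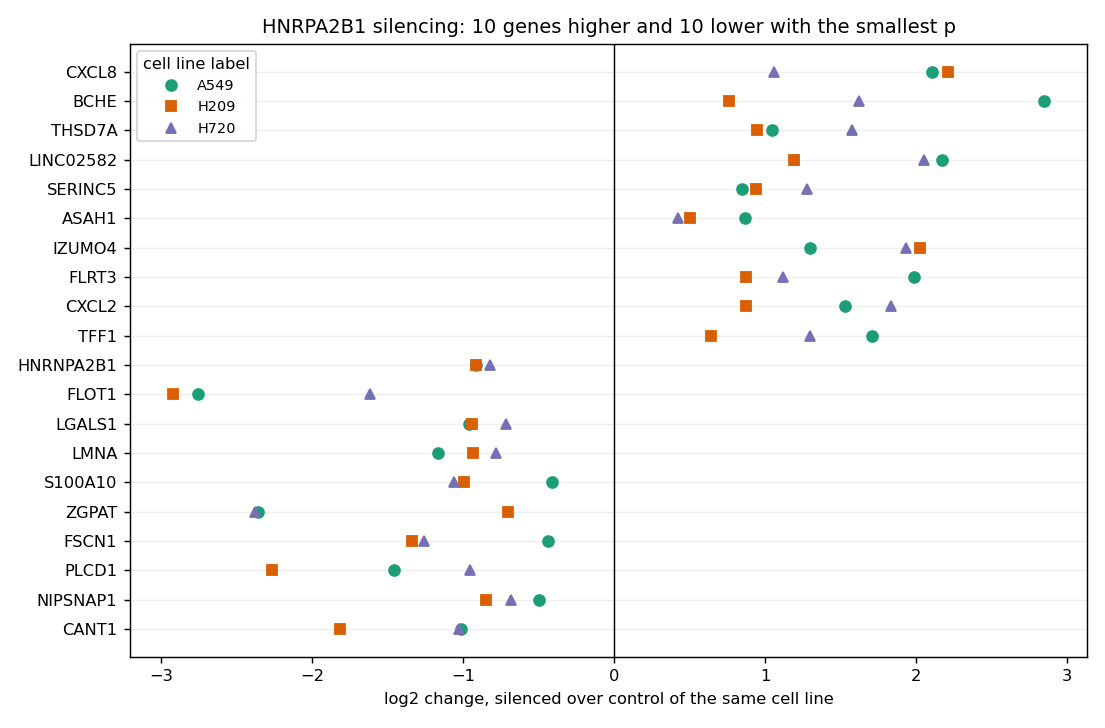
Log2 change (silenced minus control) of 20 named genes in the A549, H209 and H720 pair of the HNRNPA2B1 silencing, 1 marker per cell line. Each gene lay on 1 side of 0 in all 3 lines, as the rule for naming them required, with FLOT1 lower and CXCL8 higher. Changes with a signal under 100 in 1 array of a pair, as for FLOT1 in each line and CXCL8 in H209, depend on the 32 added before the log.

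Against their 1 control array the FLAP-silenced A549 arrays had lower mitosis and DNA replication lists and higher histone, epithelial and glutathione lists. Of these 5 only the mitosis list was also called against 5 other A549 controls. Those controls are of the MK886 and HNRPA2B1 experiments, and that fit had no term for experiment or date. A difference between experiments or dates thus cannot be told apart from silencing there, whether a call was kept or lost. Of 50 G2/M genes 48 stood lower, with a median of -0.56, and 9 were lower past the threshold over the list alone against 0 over all (camera adjusted p = 5.07e-15, and adjusted p = 0.287 with an estimated correlation). They included BUB1B at -1.07 (SE 0.26), FOXM1 at -1.15 (SE 0.30), ANLN, a protein of the contractile ring, at -0.65 (SE 0.18) and TOP2A, the topoisomerase of chromosome segregation, at -0.78 (SE 0.23). The G1/S list had a median of -0.42, and 3 of 47 were lower past the threshold over the list alone against 0 over all (adjusted p = 2.30e-08, and adjusted p = 0.287 with an estimated correlation), with ORC6 of the origin recognition complex at -0.73 (SE 0.19). Histone genes had a median of 0.73, and 4 of 13 were higher past the threshold over the list alone against 0 over all (adjusted p = 0.000328, and adjusted p = 0.277 with an estimated correlation), among them H2BC5 at 1.32 (SE 0.25). The NRF2 and glutathione list had a median of 0.24, and 3 of 33 were higher past the threshold over the list alone against 1 over all (adjusted p = 2.21e-05, and adjusted p = 0.277 with an estimated correlation), namely EPHX1 at 1.89 (SE 0.27), GPX2, a glutathione peroxidase, at 1.58 (SE 0.29) and ALDH3A1, an aldehyde dehydrogenase, at 0.93 (SE 0.22). By silenced array the medians were -0.31 and -0.73 for G2/M, -0.21 and -0.59 for G1/S, 0.45 and 0.89 for histones and 0.27 and 0.26 for NRF2 genes. The ACTB 5' to 3' ratio was 0.535 in the control and 0.478 and 0.678 in the silenced arrays. Without rescaling of the deposited values the histone median was -0.26, of the other sign, with both the scale and the probe sets tested changed (3499 passed the filter at 100, against 33763). Against the 5 other A549 controls, a comparison added after the data were seen, the G2/M median was -0.37 and still called, while the G1/S (-0.12), histone (0.11) and NRF2 (-0.058) calls were lost, with ORC6 at 0.51 and EPHX1 at -0.17.

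Of the other lists called after FLAP silencing, epithelial junction and keratin genes had a median of 0.40 with 24 of 30 higher (adjusted p = 0.000604, and adjusted p = 0.287 with an estimated correlation), as with CDH1, E-cadherin, at 0.97 (SE 0.35). A549 and lung epithelial markers had a median of 0.19 and 5 of 20 were higher past the threshold over the list alone against 0 over all (adjusted p = 0.00676, and adjusted p = 0.277 with an estimated correlation), among them AGR2, a disulfide isomerase of secretory cells, at 2.00 (SE 0.36) and CEACAM6, a cell adhesion protein, at 1.80 (SE 0.39). Unfolded protein response chaperones had a median of 0.28 (adjusted p = 0.000969, and adjusted p = 0.453 with an estimated correlation), and XBP1, a factor of that response, was past the threshold over the list alone, at 1.20 (SE 0.27). Immediate early genes had a median of -0.42 (adjusted p = 0.00381, and adjusted p = 0.587 with an estimated correlation), with 2 of 32 lower past the threshold over the list alone, CCN1 and CCN2, matrix proteins induced by YAP, at -1.97 (SE 0.40) and -1.26 (SE 0.35). The hnRNP family had a median of -0.26 with 0 past the test (adjusted p = 0.000969, and adjusted p = 0.287 with an estimated correlation), as with HNRNPH3 at -0.36 (SE 0.18). Splicing factors had a median of -0.22 (adjusted p = 0.00418, and adjusted p = 0.569 with an estimated correlation), with SRRM1, a splicing coactivator, the 1 that was lower past the threshold over the list alone, with a change of -0.98 (SE 0.20). For p53 targets the median was 0.26 with 0 past the test (adjusted p = 0.0210, and adjusted p = 0.650 with an estimated correlation). Without silenced replicate 2 the calls of p53 targets (median -0.089), immediate early genes (-0.040), splicing factors (-0.023) and epithelial genes (0.25) were lost. Against the 5 other A549 controls those of epithelial genes (-0.042), A549 markers (0.27), chaperones (-0.048), hnRNP (-0.028) and splicing factors (0.073) were lost, with CDH1 at -0.997, CEACAM6 at -1.63, XBP1 at -0.41 and HNRNPH3 at 0.38, and without rescaling those of p53 targets (0.39) and immediate early genes (-0.33), with fewer probe sets tested.

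In single genes of the FLAP comparison, 27 probe sets stood higher and 1 lower past the threshold, of 33763 tested by limma, for 22 named genes with both silenced arrays on 1 side of the control. These are differences from 1 control array with a spread taken from other A549 arrays, and with the 3 FLAP arrays alone limma called 0 (888 at an unadjusted p under 0.05). CP, the copper carrier ceruloplasmin, stood at 2.94 (SE 0.35), RAD23B, a DNA damage recognition protein, at 2.48 (SE 0.20) and AQP3, a water and glycerol channel, at 2.31 (SE 0.36). In 8 of the 27 higher ones the control signal lay under 100, so the size of the change depends on the 32 added before the log and is not given. They included CHMP4B, an ESCRT protein of membrane scission (36.6 in the control), AKAP13, an anchoring protein for protein kinase A (53.7, and 586 and 1069 in the silenced arrays) and ANK3, a membrane skeleton adaptor (68.4, 383 and 635). The others named were SLC23A2, a vitamin C transporter (48.8, 325 and 381), GSEC (19.5, 334 and 393), USE1 (24.4, 381 and 332) and LARP4 (46.4, 378 and 466). Other probe sets of CHMP4B, USE1 and RAD23B had changes of the other sign. COTL1, coactosin-like protein, which binds 5-lipoxygenase, was the 1 lower, from 13536 to a mean of 6339, a log2 change of -1.09 (SE 0.18). It was also the 1 member of the 5-lipoxygenase list past the threshold, and that list was not called (median 0.046, adjusted p = 0.586). In 22 of the 28 probe sets the single control array lay outside the range of the 10 other A549 arrays. Silenced arrays 1 and 2 did so in 14 and 8, and both at once in 7. CHMP4B stood at 36.6 in the control, 813 and 535 in the silenced arrays and 243 to 1182 in the other A549 arrays, and RAD23B at 1418, 7942 and 8220 against 6514 to 9343. FN1, the matrix protein fibronectin, in 3 probe sets, 1 of AGR2 and LXN, a carboxypeptidase inhibitor, all singled out after their values were seen, stood higher with the control inside and both silenced arrays outside that range. The first FN1 probe set stood at 4385 in the control, 10752 and 12075 in the silenced arrays and 2375 to 10373 in the others. Without silenced replicate 1, 200 probe sets were higher and 155 lower past the threshold, without silenced replicate 2, 10 and 1, and against the 5 other A549 controls 2 and 7. Against these controls AKAP13 (-0.23), CP (-0.81), LARP4 (-0.36), ANK3 (-0.52), SLC23A2 (-0.19) and COTL1 (0.93) had the other sign. That comparison mixes silencing with differences between experiments. Limma called 3 of the 3499 probe sets that passed the filter without rescaling, where scale and filter changed together. It called 0 without a trend, where 2159 had an unadjusted p under 0.05.

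**Figure D4:**
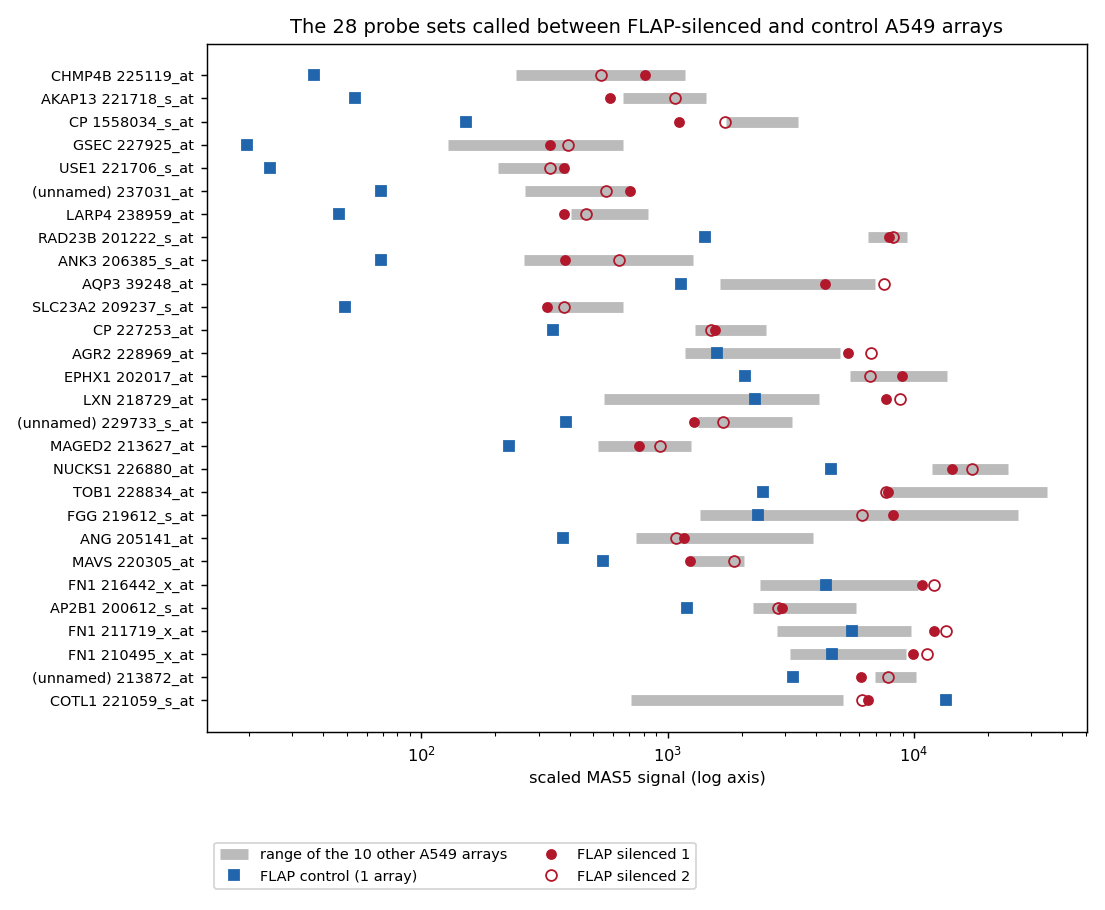
Scaled signal, on a log axis, of the 28 probe sets called in the FLAP comparison, with the control as a blue square, silenced arrays 1 and 2 as red markers and the range of the 10 other A549 arrays as a grey bar. The control lay outside the grey bar in 22 probe sets, silenced arrays 1 and 2 in 14 and 8, and both silenced arrays at once in 7.

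The drug and the siRNA aim at the same protein, so their changes in A549 were compared across genes, with separate control arrays. Over 13768 genes the changes had Pearson r = 0.00653 and Spearman rho = 0.0201, and 50.5% had the same sign, where genes are not independent replicates. Noise on either side draws r toward 0. With MK886 limma gave 1462 probe sets an unadjusted p under 0.05, where chance gives about 1595. The FLAP changes rest on 1 control array. An r near 0 thus does not show that the drug and the siRNA act differently. Between the 2 silenced arrays taken alone the SD of r was 0.0191. G2/M genes stood lower in both comparisons (medians -0.14 and -0.56), while ATF4 and CHOP genes had medians of 0.32 with MK886 and -0.11 with FLAP silencing, where the list was not called (adjusted p = 0.0929). The cholesterol list had 0.38 and 0.11 (not called with silencing, adjusted p = 0.586). In the 5-lipoxygenase list itself the median was 0.14 with MK886 (adjusted p = 0.177) and 0.046 with silencing, called in neither. With the first MK886 date alone r was -0.0234, and with a filter at a mean signal of 300 it was 0.0369.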

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

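The tests of explanations in this part and the splits that balance the A549 dates were chosen after the results were seen, while the other splits of the arrays and the search for single arrays far from their group were planned.

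In A549 MK886 replicate 2, 3 of the named genes lay far from the other 3 MK886 arrays. NIBAN1 had a scaled signal of 698 against 498 to 509, POU2F2 218 against 49.0 to 69.3 and SREBF2 1133 against 567 to 634. Such gaps were found in 3 of 86 groups searched, and chance gives about 4.3. Between the lines, the ATF4 and CHOP list (A549 minus H720, median -0.49) and the ribosomal list (-0.35) differed by the test of the difference with camera, though not with an estimated correlation (adjusted p = 0.942 for both). Without both H720 arrays numbered 2 the medians were -0.21 and -0.089, and neither was called.

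The first pattern is that replicates 3 and 4 of H720 alone called 5536 probe sets (2863 higher, 2673 lower), against 0 with replicate 2. Of these, 46.8% had the same sign in the replicate 2 pair (r = -0.149 over the called probe sets). As sources MK886, the lower ACTB ratio and a batch of replicates 3 and 4 cannot be told apart by this value, since it rests on 1 pair, deposited at another scale. All 20 ATF4 list genes among these calls had the same sign in the replicate 2 pair, as MK886 would need. This was largely bound to follow, since the list was singled out for standing higher over all 3 pairs, most in the replicate 2 pair. The ACTB ratio moved the same way in all 3 pairs too.

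The second pattern is the higher ATF4 and CHOP list with MK886 in both lines. In A549 lower RNA integrity of the MK886 arrays is argued against by the median of 0.44 on the first date, where the ACTB ratio of the MK886 arrays was higher than that of the controls. In H720 lower RNA integrity cannot be told apart from the drug, since the ACTB ratio nearly follows the treatment (variance inflation 13.6). With that ratio as a covariate the mean of the list per array still differed by 2.40 (95% interval 0.86 to 3.95, and 0.85 with 0.16 to 1.53 without it). Within each group the ratio differed mainly between replicate 2 and the others. It was 0.555 against 0.651 and 0.648 in the control and 0.373 against 0.297 and 0.281 in the MK886 arrays. The adjustment thus rests on the arrays deposited at another scale and does not separate the ratio from the drug. The pair with the smallest fall of the ratio (-0.182) had the largest median (1.28), but it is that same replicate 2 pair. The arrays are also too few to settle the question, as the interval reached -0.21 without control replicate 3 and -0.27 without MK886 replicate 4. The lower scale of H720 replicate 2 is argued against by medians of at least 0.44 in the pairs of replicates 3 and 4. Serum-free medium cannot be told apart from the drug, since 0 control arrays are labelled with it and the medium of A549 is not given. MK886 may be the source, as a hypothesis, with 0.18 the lowest median of the 3 pairs and 2 dates.

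The third pattern is the 28 calls of the FLAP comparison. The lone control array standing apart may be a source. It lay outside the range of the 10 other A549 arrays in 22 of the calls, against 14 and 8 for silenced arrays 1 and 2 and 7 for both at once. The calls were picked by the gap between that control and the silenced arrays. This favours a control outside the range, so these counts do not decide it. Over all probe sets the control lay outside in 24.8% (26.8% and 21.8% for the silenced arrays, 18.2% expected of 1 more array). Of the 6 calls with the control inside the range, 5 had both silenced arrays outside it (FN1 in 3 probe sets, AGR2 and LXN). That decides nothing about the control as a source either, since these were picked by where their control lay. For the 20 calls with a control signal of at least 100 the median signal over the FLAP arrays was 5659, though 1 probe set of CP had a control of 151. These calls were picked by their control signal. That median thus does not decide whether the low deposited scale of these arrays is a source. For the other 8, with a control near the background (median signal 330), that scale cannot be told apart from other sources either. Loss of FLAP stays open and cannot be told apart from the other differences between these arrays, since the interval of the ALOX5AP change reached 1.14.

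Other splits of the same arrays into groups of the same sizes gave the following. With a real count of 0 probe sets every split is as large whatever the data, so the shares for the counts decide nothing. In H720 the 10 splits are too few for a share under 0.05, with a count of 0 for the real split and at most 0 in the others (10 of 10 as large), 5 lists against at most 13 (8 of 10 as large) and an ATF4 median of 0.76 against at most 0.48 (1 of 10). Among the 4 splits that part all 3 pairs the highest other number of lists was 6, and the 4 splits with 11 to 13 lists kept both arrays numbered 2 together. In A549 the count was 0 (35 of 35 as large), and chance was not excluded for the lists (5 against at most 16, 14 of 35). For the ATF4 median 1 of 35 splits was as far from 0, the real one (0.32, against at most 0.26 in the others). Since arrays of different dates differ, the ATF4 median is better compared with the 18 splits that balance the dates, which are too few for a share under 0.05 (1 of 18, 0.32 against at most 0.26). Among the 8 A549 splits that part all 4 pairs the highest other number of lists was 8, and the others part fewer pairs. The A549 split along the dates called 11538 probe sets, which points to a difference between the dates that the covariate takes out, and the others called at most 0. For the difference between lines the count was 0 against at most 7 (100 of 100 splits as large), and chance was not excluded for the lists (2 against at most 17, 99 of 100). For HNRPA2B1 silencing the 10 splits are too few, with a count of 0 (10 of 10 as large) and 9 lists (4 of 10). With cell line as a block, a split that parts 1 pair holds only the silencing change of that line. The highest split, with 54 calls and 17 lists, is thus the change of the A549 pair, with its ATF4 median of 0.58. Such splits, which also repeat each other, do not measure chance. Among splits that part all 3 pairs the highest number of lists was 12.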

How the results depend on the processing

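Alternatives that were chosen after seeing the data are named as added. Of the recomputed values that answer a comparison, 98 stayed within 1.5 times the count or within the spread and 33 moved. A count of 0 that stayed 0 is among the 98. Of the recomputed list medians, 387 kept direction and call, 63 kept direction and lost the call and 14 reversed. Of the recomputed changes of named genes 3040 kept their direction and their side of the threshold, 104 came past it, 54 fell short of it and 28 reversed. Only FLAP silencing had called probe sets, so in the other comparisons a named gene had no call to lose. With camera at the preset correlation the ATF4 and CHOP list kept its call in each of 17 alternatives in H720 (median 0.44 to 2.08) and 20 in A549 (0.17 to 0.44). Where no cause is given, the cause was not tested.

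Counts when 1 array or pair was left out ranged from 0 to 6 in H720, 0 to 7 in A549, 0 to 94 for the difference, 0 to 17 for HNRPA2B1 silencing and 11 to 355 for FLAP. In H720, replicates 3 and 4 alone (added) gave 5536, in A549 the first date alone gave 2, and for the difference a pseudocount of 8 gave 2 and leaving out both H720 arrays numbered 2 (added) 578. For FLAP the deposited values gave 3 (with 3499 probe sets past the filter), eBayes without a trend 0 (2159 at an unadjusted p under 0.05 with limma), the 3 FLAP arrays alone 0 (888, with fewer arrays for the spread), all other arrays for the spread 9 and the silenced arrays against 5 other A549 controls (added) 9. Lists called with an estimated correlation were 0 in each of the 5 comparisons, and with fry 0 in H720, 1 in A549, 0 for the difference, 0 for HNRPA2B1 and 3 for FLAP. With the mean over the probe sets of a gene only 3 of the 5 lists called in A549 and 5 of the 9 called for HNRPA2B1 kept the call, and no others gained it. For the difference 7 were then called, including the 2 called before. With a trend of the variance (added) 5 lists were called for the difference. The correlation of MK886 and FLAP changes was 0.0369 with the filter at 300 and -0.0234 on the first date.

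List medians that reversed were, in H720, G1/S 0.095 and oxidative phosphorylation 0.14 without MK886 replicate 2, and G1/S 0.020 and ribosomal -0.010 in replicates 3 and 4. With 1 array left out G1/S ranged from -0.25 to 0.095 and oxidative phosphorylation from -0.28 to 0.14. In A549 the ribosomal median was 0.035 on the second date. For HNRPA2B1 without replicate 1 they were ATF4 -0.11, NF-kB -0.15 and EGFR and MAPK -0.059, with ranges over the pairs left out from -0.11 to 0.32, -0.15 to 0.27 and -0.059 to 0.38. For FLAP they were histones -0.26 without rescaling (fewer probe sets tested) and p53 -0.089 without silenced replicate 2 (range -0.089 to 0.58). Against 5 other controls, which are of other experiments, they were chaperones -0.048, NRF2 -0.058, splicing 0.073 and epithelial -0.042. Named genes that reversed there were AKAP13 -0.23, CP -0.81, LARP4 -0.36, ANK3 -0.52, SLC23A2 -0.19, COTL1 0.93, XBP1 -0.41, PDIA3 -0.070, DNAJB9 -0.084, HSP90B1 -0.048, EPHX1 -0.17, ORC6 0.51, UHRF1 0.17, HNRNPH3 0.38, SF1 0.35, TRA2A 0.068, SRSF6 0.35, DSC2 -0.38, CDH1 -0.997, CEACAM6 -1.63, H2AC17 -0.14. In H720 with the ACTB ratio as a covariate (added), which nearly follows the treatment, SLC35F6 -0.86, CCNE2 0.015, AP1S3 0.80, PRPS2 0.15, E2F1 -1.33, FOXM1 -1.26, SDHD 0.71 reversed. The probe set of ALOX5AP lay below the filter at 300 and, without rescaling, below that at 100, and gave no value there. Signals under 100 limit the genes given without a change, and the number of arrays limits the rest.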

Other observations

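The test of each list below was planned, while the comparisons across genes between experiments other than MK886 and FLAP silencing, and those between cell lines, were chosen after the data were seen. With MK886 the chaperones of the unfolded protein response, such as those that fold proteins in the endoplasmic reticulum, were not called. Their median was 0.10 in H720 (camera adjusted p = 0.318) and 0.029 in A549 (adjusted p = 0.576). Apoptosis regulators had medians of 0.034 and 0.034 (adjusted p = 0.980 and 0.978), and p53 targets 0.012 and 0.086 (adjusted p = 0.980 and 0.478). Epithelial junction and keratin genes in H720 had a median of 0.27 (adjusted p = 0.0716), and with the replicate numbers as a block of pairs the adjusted p was 0.0281, while the adjusted p = 0.848 with an estimated correlation and no block. Interferon response genes had A549 medians of -0.0044 on the first and 0.42 on the second date (adjusted p = 0.177 over both). Across 11436 genes the MK886 changes of H720 and A549 had r = 0.118, with 55.3% of the same sign, where genes are not independent replicates.

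Immediate early genes after HNRNPA2B1 silencing had medians of 1.05, -0.34 and -0.32 in A549, H209 and H720, and the list was not called (adjusted p = 0.171). Across 14071 genes the changes after HNRNPA2B1 and FLAP silencing had r = 0.0620, and across 13836 genes those after MK886 in A549 and HNRNPA2B1 silencing r = 0.000498. The arrays labelled H209 and H720 were close, and whether the H209 label is right, on which each value by line rests, was not settled. Between their control arrays in the HNRPA2B1 experiment 56 probe sets differed by more than 8-fold, against 1339 between A549 and H209 and 1221 between A549 and H720. Only 2 probe sets were below 100 in both H209 arrays and above 300 in all 8 H720 arrays, and 0 the other way, while 66 were below 100 in A549 and above 300 in all H720 arrays. With the H720 control arrays of the MK886 experiment the H209 control correlated at r = 0.910, 0.899 and 0.904 and the HNRPA2B1 control labelled H720 at 0.897, 0.897 and 0.899. With the MK886 arrays these were 0.911, 0.884 and 0.883 against 0.884, 0.892 and 0.890, so neither control array was the closer one throughout. Of the silenced arrays, the one labelled H209 was closer than the one labelled H720 to each of these H720 arrays. With the controls r was 0.904, 0.906 and 0.910 against 0.873, 0.870 and 0.872. With the MK886 arrays it was 0.905, 0.889 and 0.888 against 0.866, 0.861 and 0.858.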
